A study of Rattus norvegicus with 6 samples.

How the data were processed

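Total RNA from the renal cortex of male Sprague-Dawley rats, bought at 5 weeks of age, was measured on 6 one-colour Agilent microarrays, 1 array per animal. Per the labels' protocols, 3 animals received corn oil, the vehicle, for 4 weeks and 3 received 2,2-bis(bromomethyl)-1,3-propanediol (BBMP), a brominated diol, at 1000 mg/kg/day for 4 weeks. The design text calls the samples of a group biological replicates.

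Per the labels' protocols, RNA was labelled with Cy3. Per the file headers, each array was read with Agilent Feature Extraction 10.7.1.1, and the submitters' processing notes name version 10.7. Per the file headers, the deposited scanner files hold intensity on a linear scale: a processed signal with background removed and detrended, and the raw median signal with its local background. They also hold flags, scored 0 or 1, for a spot that is well above background, saturated or an outlier. The authors' deposited table of the whole series gives 1 ratio per probe and array, and how it was made is not stated in it. Each column was set against each scanner file and equals the processed signal of 1 file of the same group divided by that array's 75th percentile, with no centring per gene. The medians of its columns lay between 0.1064 and 0.1131. Each column matched the scanner file of another sample of its own group, in the same rotation in both groups, so replicate numbers are uncertain, while group membership is not touched. The scanner files were used, with the sample given for each file.

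The arrays carried 61657 probes that the files do not mark as controls. Of these, 84 carry ERCC sequences, which are synthetic spike-in controls and match no rat gene, and these were left out after the first results were seen. Of the remaining 61573 probes, 10 were left out for an outlier flag. The log2 processed signal minus the array's 75th percentile over the remaining probes was the measured value. A probe was tested if it was well above background on all 3 arrays of at least 1 group, which held for 42657 probes. Genes were named by matching the unversioned RefSeq accession to a table of the GRCr8 assembly, used for names only, which named 27460 probes. The design file of the array is based on rn4, and no coordinates were used. Other sequences kept the name in the file. Each gene was represented by its probe with the highest mean signal, giving 31582 genes or sequences, of which 12077 had a name from the table.

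The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates), and p-values were adjusted by the Benjamini-Hochberg method. A gene is called changed, higher or lower where its adjusted p was under 0.05, and values are BBMP minus control. The 34 gene lists covered toxicity pathways, kidney cell types, and tissues and states that a cortex sample could also hold. They were tested with limma's camera at a preset correlation of 0.01, which compares a list with all other genes, with an estimated correlation and limma's fry as alternatives. Fry does not compare a list with other genes, so passing it does not show that a list moved more than they did. The test, the lists, the rule for naming genes and most alternatives were fixed before the data were examined. The alternatives that kept the ERCC probes, used slide row 1 alone or counted only genes well above background on all arrays with at least 2-fold change were added later. Named genes were the 12 called higher and the 12 called lower with the largest change among named genes well above background on all 6 arrays with groups that do not overlap, and up to 4 members of each described list. The 5 largest bounds in each direction were added from called genes that were not well above background on any array of 1 group. Up to 12 lists were described: first those past the threshold, then those with the highest share of called members. Any other gene named was chosen after its values were seen. Some genes that the rule chose are not reported here.

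In simulated data with independent noise, 67, 67 and 66 of the 31582 genes were changed 1.5-fold, 2-fold and 4-fold. The fit recovered 47.8%, 56.7% and 86.4% of them, with 3 false calls. Far fewer genes were changed there than were called in the real data. The adjustment depends on that share, so these rates do not carry over to the real comparison. With 3 arrays per group, the number of arrays limits the precision. The alternatives covered background correction, normalization, the authors' ratio table, the filter on dim probes, the choice of probe, blocks for replicate number and slide row, array weights, the empirical Bayes step, a 2-fold minimum and leaving out each array. The planned background correction was to use the mean signal, and the median signal was used in its place. Normexp, the background correction used, added an offset of 50 to each signal, which shrinks log2 changes of dim probes by construction. Python 3.11.15 and matplotlib 3.10.9 drew the plots.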

Results

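Gene expression in the renal cortex was measured in 3 control rats and 3 rats given BBMP, and the comparison asks which genes the compound changed. Between 67.2% and 72.7% of probes were well above background on each array. The 75th percentile of the processed signal lay between 942 and 949 on the control arrays and between 1244 and 1259 on the BBMP arrays. Correlations across genes, which are not independent replicates, had a median of 0.993 between arrays of the same group and 0.989 between groups. All 3 control arrays were on slide 1 and scan 1, and all 3 BBMP arrays were on slide 2 and scan 2, so treatment, slide and scan cannot be told apart.

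Gstp1 and Ephx1, both in the list of NRF2 targets, were among the 12 largest increases in named genes that were called, well above background on all 6 arrays and without overlap of the groups. Gstp1, a glutathione transferase, was 2.38-fold higher, with a normalized log2 signal of 5.92 ± 0.22 in control and 7.18 ± 0.29 in BBMP samples (SD, n = 3 each; limma adjusted p = 0.0153). Ephx1, the microsomal epoxide hydrolase, was 2.02-fold higher, at 3.08 ± 0.15 in control and 4.09 ± 0.11 in BBMP samples (SD, n = 3 each; limma adjusted p = 0.0108). Gabbr2, a GABA-B receptor subunit, had the largest decrease among genes that met the same conditions and was 3.56-fold lower, at 1.19 ± 0.54 in control and -0.65 ± 0.24 in BBMP samples (SD, n = 3 each; limma adjusted p = 0.0169). Exosc3, a subunit of the RNA exosome, was 2.94-fold lower, at 0.23 ± 0.20 in control and -1.33 ± 0.07 in BBMP samples (SD, n = 3 each; limma adjusted p = 0.0108).

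Of 31582 genes or sequences tested, 5653 changed, 3228 higher and 2425 lower in the BBMP group. Most changes were small: the median size among called genes was 0.45 on the log2 scale, and 219 changed at least 2-fold, 181 higher and 38 lower. The groups did not overlap in 43.6% of genes, where chance gives 10% for 3 arrays against 3. The share called higher depended on the scaling: it was 57.1% here, 49.0% with quantile normalization, 46.6% with cyclic loess, 36.3% with normexp background correction and 35.8% with median scaling. Among genes well above background on all 6 arrays, 67 rose and 26 fell at least 2-fold, against 33 and 46 with cyclic loess, 42 and 41 with quantile normalization, 42 and 41 with median scaling, and 13 and 13 with normexp. With normexp, which replaced both the processed signal and its background correction, 27 genes changed at least 2-fold, 48.1% of them higher. By construction its offset of 50 shrinks changes of dim genes and can pull them toward lower in BBMP. Their smaller changes with normexp therefore do not decide whether they changed. Of 1135 called named genes with several tested probes, all probes moved the same way in 863, another probe was also called the same way in 446, and another was called the opposite way in 40.

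**Figure D1:**
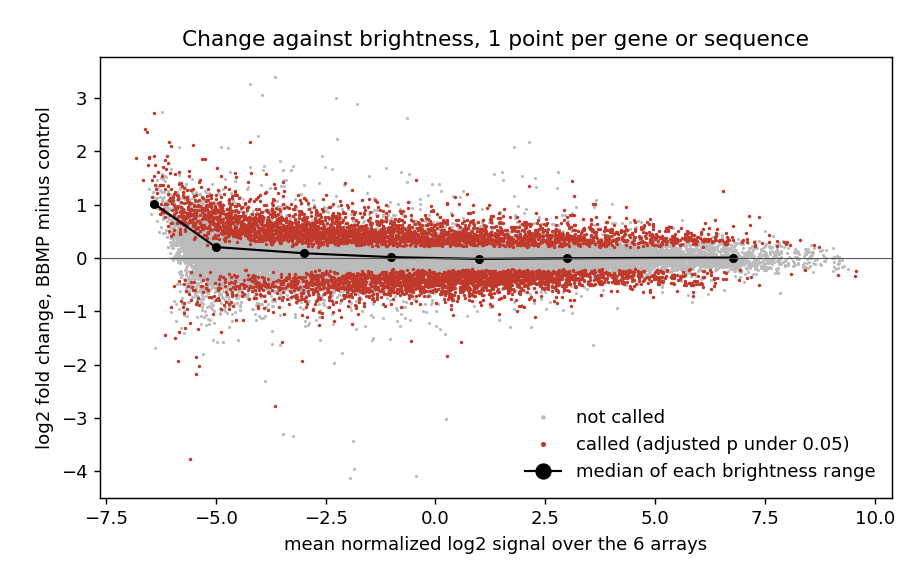
Log2 fold change (BBMP minus control) against the mean normalized log2 signal over the 6 arrays, 1 point per gene or sequence, with called genes in red and the median of each brightness range as a black line. The median change was 1.02 in the dimmest range and lay between -0.017 and 0.21 in the other ranges.

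Rarres2, which encodes the adipokine chemerin, rose 2.24-fold (limma adjusted p = 0.0229), and Slc39a4, a zinc importer, rose 2.20-fold (adjusted p = 0.0165). Mogat2, an acyltransferase of triglyceride synthesis, rose 2.08-fold (adjusted p = 0.0409). Phkg1, a subunit of phosphorylase kinase, rose 2.97-fold and Htra4 2.45-fold, with the olfactory receptor genes Or4f14d and Or13c7d at 2.05-fold and 2.04-fold. Tigd3, B3gnt8 and Ago1 rose between 2.00-fold and 2.18-fold. Of these dim genes, Htra4, Or13c7d and Ago1 lay in a brightness range where the median log2 change of all genes was 0.21, and Phkg1, Tigd3, B3gnt8 and Or4f14d in one where it was 0.09. With normexp their log2 changes were 0.53 for Phkg1, 0.15 for Htra4, 0.18 for Or13c7d and 0.075 for Ago1, none of them called, and 0.70 for Tigd3, 0.36 for B3gnt8 and 0.57 for Or4f14d. Phkg1, Tigd3 and Ago1 narrowly missed the threshold with quantile normalization, median scaling and cyclic loess (adjusted p from 0.0517 to 0.0683), at log2 changes of 1.40 to 1.49 for Phkg1, 1.01 to 1.05 for Tigd3 and 0.86 to 0.93 for Ago1. Htra4 did so with quantile normalization and cyclic loess, at 1.16 and 1.13. Ihh, a hedgehog ligand, fell 2.07-fold (adjusted p = 0.0201), and Cldn10, a claudin of the thick ascending limb, fell 1.88-fold (adjusted p = 0.0268). Clca4 fell 2.15-fold, the mitotic kinesin gene Kif15 fell 2.01-fold and Pawr fell 2.04-fold. Gpr158, Or5bb12, Ocm, Rps12l4 and the metallothionein gene Mt3 fell between 1.91-fold and 2.25-fold. Gpr158 was at -0.68 on the log2 scale with normexp, still called, and Ihh at -0.52 with the mean of its probes, where it did not pass; its 4 other probes were also negative, and 1 was called.

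Targets of NRF2, the transcription factor of the antioxidant response, included 7 of 36 tested members called higher and 0 called lower, and also 7 higher when adjusted over the list alone. Besides Gstp1 and Ephx1, these included Nqo1, a quinone reductase, at 1.99-fold, the aldehyde reductase gene Akr7a3 at 1.72-fold, and the efflux transporter genes Abcc4 at 1.64-fold and Abcc2 at 1.57-fold. As a set the list did not pass camera, which compares it with other genes (adjusted p = 0.372, and adjusted p = 0.864 with an estimated correlation). Limma's fry, which makes no such comparison, gave an adjusted p of 0.0278 for movement in 1 direction. Of all alternatives, the list NRF2 targets passed camera only with normexp (adjusted p = 0.00361) and with no filter on dim probes (0.0398), in a range of 0.00361 to 0.864 with fry included. Called NRF2 targets numbered 4 without empirical Bayes moderation, 4 without BBMP replicate 1, 4 without BBMP replicate 3 and 0 without BBMP replicate 2, where 8 had an unadjusted p under 0.05. Fatty acid and triglyceride synthesis had 5 of 14 members called higher and 1 lower, the same numbers as when adjusted over the list alone. Acaca, acetyl-CoA carboxylase, rose 1.65-fold, Dgat2 1.34-fold, Dgat1 1.28-fold and Fads2 1.25-fold, with Fasn also higher at 1.35-fold and Acly lower at 1.30-fold. Fatty acid and triglyceride synthesis did not pass camera (adjusted p = 0.372, and adjusted p = 0.864 with an estimated correlation) except with normexp (0.0227) and no filter on dim probes (0.0398), and passed fry (adjusted p = 0.0133, the lowest in a range up to 0.864). Its 5 members called higher became 3 with median scaling, no filter on dim probes or without control replicate 3, 2 without control replicate 1, and 1 without control replicate 2 or BBMP replicate 3. Without BBMP replicate 1 or 2, limma called 0 of its members, with 6 and 7 at an unadjusted p under 0.05. Acaca was at 0.35 on the log2 scale with normexp, still called, and Fads2 did not pass with median scaling, at 0.25 against 0.32.

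Genes of the interferon response and of antigen presentation formed the 1 list past the camera threshold, in the lower direction (adjusted p = 0.0167, and adjusted p = 0.864 with an estimated correlation). The list interferon response and antigen processing did not pass with normexp (adjusted p = 0.196), cyclic loess (0.061), no filter on dim probes (0.133), or without control replicate 1 (0.161) or BBMP replicate 2 (0.152), nor with slide row as a block (0.256) or slide row 1 alone (0.235), nor with fry (0.433). Of its 30 members, 2 fell and 0 rose, also when adjusted over the list alone: the chemokine gene Cxcl9, lower by 1.47-fold, and Mx2, lower by 1.29-fold. With median scaling 4 members fell and 0 rose, with normexp 9 fell and 0 rose, and without control replicate 1 or with the mean of all probes 1 fell. Without control replicate 2 or any 1 BBMP replicate, limma called 0, with 4 to 10 at an unadjusted p under 0.05. Psmb10 and Dhx58 did not pass, at log2 differences of -0.24 ± 0.07 and -0.54 ± 0.18 (SE), and 1 of the other probes of Dhx58 had the opposite sign. Among collecting duct principal cell markers, 3 of 13 fell and 0 rose: the water channel gene Aqp4 by 1.53-fold, Elf5 by 1.44-fold and Hsd11b2, which inactivates corticosterone, by 1.40-fold. Of the other probes of Aqp4, 1 was also called lower (adjusted p = 0.0458) and 1 that was not called had the opposite sign (0.22). Aqp2 did not pass, at a log2 difference of 0.011 ± 0.12 (SE), nor did Scnn1a, at 0.27 ± 0.14. The other probe of Scnn1a was called higher, at 0.60 ± 0.15 (SE; limma p adjusted over all probes = 0.0458). Among podocyte markers, 3 of 15 rose and 0 fell, with Synpo higher by 1.32-fold and Nes by 0.58 on the log2 scale, while Tdrd5 did not pass (0.35 ± 0.14, SE). With normexp Hsd11b2 and Synpo did not pass, at -0.39 against -0.48 and at 0.16 against 0.40 on the log2 scale. Adjusted over the list alone, the counts of both lists were the same. Neither list passed camera (adjusted p = 0.372 and 0.601). Podocyte markers called higher numbered 1 with no filter on dim probes, the mean of all probes or no empirical Bayes moderation. Without control replicate 2 or any 1 BBMP replicate, limma called 0 members of either list, with 3 to 4 at an unadjusted p under 0.05, and without control replicate 1 it called 2 collecting duct and 1 podocyte marker.

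Genes of p53 and DNA damage response, G1/S transition and cholesterol synthesis moved both ways. Of 26 p53 targets, 3 rose (Ephx1, Phlda3 at 1.31-fold and Sesn2 at 1.45-fold) and Ptp4a1 fell 1.37-fold, with the same counts when adjusted over the list alone, while Cdkn1a did not pass (log2 difference 0.19 ± 0.06, SE). With cyclic loess 2 p53 targets rose and 3 fell, and Phlda3 did not pass there or with normexp, at 0.25 and 0.16 against 0.39 on the log2 scale. Of 30 genes of G1/S transition and DNA replication, 3 rose and 3 fell (3 and 4 adjusted over the list alone), with Cdc6 higher by 1.83-fold, Gins2 lower by 1.53-fold, Dut by 1.44-fold and Mcm4 by 1.26-fold. Of the other probes of Mcm4, neither called, 1 had the opposite sign and 1 the same. Cdc6 and Gins2 are dim, and with normexp the log2 change of Cdc6 went from 0.87 to -0.018 and was not called. With normexp 2 of the G1/S genes rose and 7 fell, and with median scaling 2 rose and 6 fell. Of 23 cholesterol synthesis genes, 3 rose and 3 fell (3 and 4 adjusted over the list alone): Mvk rose 1.35-fold, while Insig1 fell 1.32-fold and Sc5d 1.45-fold; with normexp 3 of the list rose and 5 fell, and with median scaling 2 rose and 5 fell. Of 14 genes of vitamin D, calcium and phosphate regulation, Pth1r, the parathyroid hormone receptor, rose 1.53-fold, while Atp2b1 fell 1.31-fold and the calcium channel gene Trpv5 1.36-fold, although its other probe had the opposite sign; adjusted over the list alone, 3 rose and 4 fell, and Kl was at -0.30 ± 0.08 (SE). With normexp 2 of this list rose and 4 fell, with median scaling 1 rose and 4 fell, and with the mean of all probes 2 rose and 1 fell. Of 18 hypoxia response genes, 3 fell: the glucose transporter gene Slc2a1 by 1.37-fold, Kdm3a by 1.21-fold and Vegfa, which fell by 0.26 on the log2 scale although all 5 of its other probes had the opposite sign and 2 of them were called, and Ldha did not pass (0.26 ± 0.08, SE). Only 1 hypoxia gene fell with quantile normalization, cyclic loess, the percentile over detected probes, no filter on dim probes or the mean of all probes, and with normexp 1 rose and 3 fell. Kdm3a lost its call in each of these settings, at -0.25 to -0.27 on the log2 scale and at -0.13 with normexp. Vegfa lost its call with quantile normalization, cyclic loess and the percentile over detected probes, at -0.27, -0.26 and -0.25. Of 13 heat shock genes, Hspb1 rose 1.44-fold and Hsp90aa1 fell 1.25-fold, while Hspb8 and Hsph1 did not pass (0.46 ± 0.18 and -0.24 ± 0.09, SE). The hypoxia and heat shock counts were the same when adjusted over the list alone. Of 7 adrenal gland markers tested, Th rose 1.28-fold and Cyp21a1 1.51-fold, with another probe of Th of the opposite sign, and 3 rose when adjusted over the list alone. Pnmt and Hsd3b1 did not pass over all genes (0.25 ± 0.08 and 0.81 ± 0.40, SE). None of these lists passed camera (adjusted p from 0.372 to 0.824), and the list adrenal gland markers passed fry (adjusted p = 0.0155, the lowest in a range up to 0.864). Limma called 26 distinct genes of these 7 lists, against 18 without control replicate 3, 7 without control replicate 1 or BBMP replicate 3, 5 without control replicate 2 and 4 without BBMP replicate 1. Without BBMP replicate 2 it called 0, with 44 at an unadjusted p under 0.05.

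**Figure D2:**
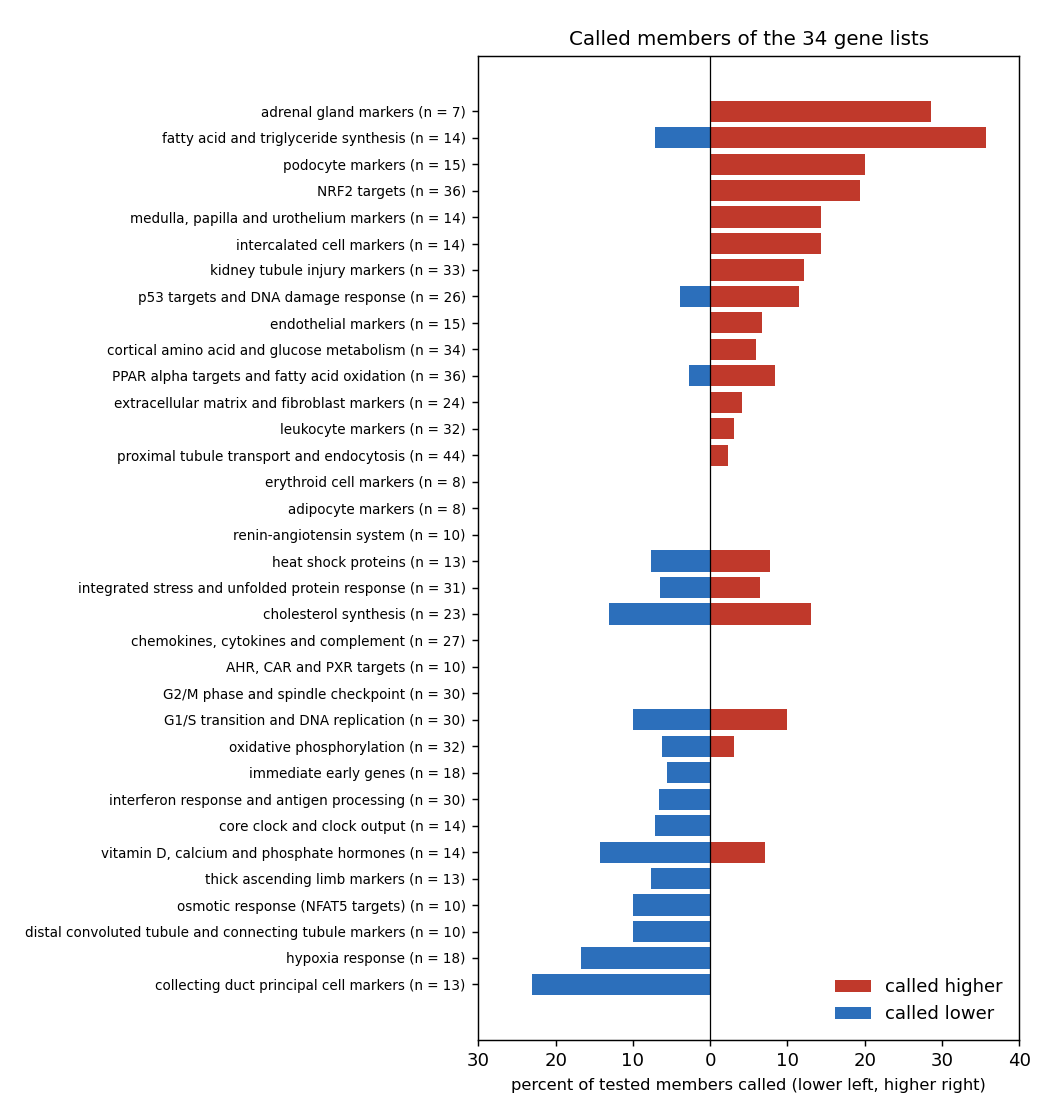
Percent of tested members called higher (red, to the right) or lower (blue, to the left) in BBMP samples, for each of the 34 gene lists, with the number tested in parentheses. Fatty acid and triglyceride synthesis had the longest bar to the right, with 5 of 14 members, and collecting duct principal cell markers the longest to the left, with 3 of 13.

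Of 44 genes of proximal tubule transport and endocytosis, 1 rose and 0 fell (0 and 0 adjusted over the list alone), against 0 and 6 with median scaling, 2 and 4 with normexp and 2 and 8 with trend and robust moderation. Of 34 genes of cortical amino acid and glucose metabolism, 2 rose and 0 fell (1 and 0 over the list alone), against 1 and 3 with median scaling, 3 and 2 with normexp and 4 and 3 with trend and robust moderation. Kidney tubule injury markers had 4 of 33 members higher and 0 lower (3 and 0 over the list alone), and PPAR alpha targets 3 of 36 higher and 1 lower (1 and 1). PPAR alpha targets had 7 higher and 1 lower with normexp and 1 and 2 with median scaling, and the injury markers 4 and 2 with normexp, 2 and 0 with median scaling and 7 and 0 with trend and robust moderation. Intercalated cell markers and markers of medulla, papilla and urothelium each had 2 of 14 higher and 0 lower. In oxidative phosphorylation, 1 of 32 rose and 2 fell, and in the integrated stress and unfolded protein response, 2 of 31 rose and 2 fell (1 and 2 over the list alone), against 2 and 6 with normexp and 1 and 3 with median scaling. One member rose and 0 fell among 15 endothelial markers, 32 leukocyte markers and 24 extracellular matrix and fibroblast markers, with 0 leukocyte markers over the list alone. One member fell and 0 rose among 13 thick ascending limb markers, 10 distal convoluted and connecting tubule markers, 10 targets of NFAT5, 14 clock genes and 18 immediate early genes; over the list alone, 2 clock genes rose and 3 fell, and 0 distal tubule markers and 0 immediate early genes changed. The other lists kept their counts when adjusted over the list alone. No member was called by limma among 30 genes of G2/M phase, 10 targets of AHR, CAR and PXR, 27 chemokines, cytokines and complement genes, 10 genes of the renin-angiotensin system, 8 adipocyte markers and 8 erythroid markers. With normexp 4 endothelial markers, 4 intercalated cell markers and 3 matrix and fibroblast markers rose and 0 fell, and 1 chemokine or complement gene rose and 3 fell. Limma called 30 distinct genes of these 22 lists, against 12 without control replicate 1, 8 without control replicate 2, 5 without BBMP replicate 1 and 7 without BBMP replicate 3. Without BBMP replicate 2 it called 0, with 85 at an unadjusted p under 0.05. None of these lists passed camera in the main fit (adjusted p from 0.372 to 0.755), but with normexp a list among them did. The median, the mean and the test differed in sign in 8 of the 34 lists, p53 targets, cholesterol synthesis and heat shock proteins among them.

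Clca2 was not well above background on any BBMP array and was at least 3.59-fold lower there (limma adjusted p = 0.0108). Or52e8b was at least 2.03-fold lower, RT1-M4, a class I histocompatibility gene, at least 1.70-fold and Kctd8 at least 1.56-fold. In the other direction, Fam217b was not well above background on any control array and was at least 2.26-fold higher in the BBMP group (limma adjusted p = 0.0217). Tex28 was at least 1.85-fold higher, Amigo3 at least 1.74-fold and Cfap161 at least 1.72-fold. Cd5, a T cell surface gene, was 1.88-fold higher. Its value is an estimate and no bound, since its own signal on each control array exceeded the lowest signal well above background there. With normexp none of these 5 higher genes was called, at log2 changes of 0.0041 for Fam217b, -0.085 for Cd5, 0.073 for Tex28, -0.018 for Amigo3 and 0.0017 for Cfap161, and Cd5 narrowly missed the threshold with quantile normalization, median scaling and cyclic loess, at 0.78, 0.83 and 0.84 against 0.91 (adjusted p = 0.0641, 0.0531 and 0.0553). The 4 lower genes kept their calls with normexp, at -0.88 for Clca2, -0.56 for Or52e8b, -0.63 for RT1-M4 and -0.47 for Kctd8. The normexp offset can pull dim genes toward lower in BBMP by construction. This contrast therefore does not show that the lower calls are firmer than the higher ones. These bounds set the mean of the brighter group against the lowest signal well above background on the arrays of the other, or against its own signal where that was higher. The first kind held 4 named genes and the second 31, 2 of which had a bound under 1 and so no fold.

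The number of called genes fell from 5653 to 3 without BBMP replicate 2, to 955 without BBMP replicate 1 and to between 1543 and 1830 without BBMP replicate 3, control replicate 1 or control replicate 2. Genes at an unadjusted limma p under 0.05 numbered 9552, 9586 and 9606 without BBMP replicates 2, 1 and 3. They numbered 9730 and 9874 without control replicates 1 and 2. These counts are close, so the drop to 3 turned on the adjusted threshold and does not show that BBMP replicate 2 carried the result. With the row of the array on its slide as a block, where row 1 held control 3 and the BBMP arrays and row 2 held controls 1 and 2, limma called 0 genes, with 7286 at an unadjusted p under 0.05 against 11559 without the block, and 0 genes with row 1 alone, with 7176.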

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

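The tests on ERCC probes and on further probes of the called genes were chosen after the results were seen. Of the 84 ERCC probes, whose sequences match no rat gene, 9 were well above background on all arrays of a group. Of these, 4 were higher on every BBMP array than on any control array, and 3 of the 4 passed the limma threshold, with log2 differences of 0.69 for ERCC-00111_144, 0.55 for ERCC-00019_219 and 0.51 for ERCC-00092_138. ERCC-00018_67 at -2.47 and ERCC-00113_271 at -1.85 passed in the other direction.

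The real split of the 6 arrays called 5653 genes and the highest of the other splits called 1, so 1 of the 10 splits gave as many, and 10 splits are too few for a share under 0.05. After scaling, the E1A spike-ins, added in amounts set by the kit, lay at a median log2 difference of -0.40 between the slides. That median mirrors the scaling, since the 75th percentile was 942 to 949 on control and 1244 to 1259 on BBMP arrays. Against these spike-ins the rat signal was brighter on the BBMP arrays, so the split into higher and lower rests on the scaling. Around their median the 8 spike-ins had an SD of 0.0608 (log2), against a median size of 1.18 for genes changed at least 2-fold. A bound on this SD had been set before it was computed, although the values of 2 spike-ins had been seen, and it was too narrow a test, because ERCC probes without a rat target also differed: 55.6% were called (exact 95% interval 21.2 to 86.3) against 16.0% of genes of like brightness (two-sided Fisher's exact p = 0.00747), so slide and treatment cannot be told apart. For genes called under 2-fold, 79.0% of 1635 other probes moved the way of the main probe, against 67.3% for genes not called, which argues against hybridization of single probes as the whole cause of those calls. All 12 other probes of 7 named genes called at least 2-fold also moved the way of the main probe, but 7 of 219 genes are too few to exclude it for the rest. Cross-hybridization of changed rat RNA to the ERCC probes, a difference between slides and an effect of BBMP stay open.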

How the results depend on the processing

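The alternatives that kept the ERCC probes or used slide row 1 alone, and the count of NRF2 targets as a result of its own, were chosen after seeing the data. With the authors' ratio table, each of the 78 genes chosen by the naming rule kept its direction and its side of the threshold. That was so by construction, since the ratios are the same signal with the same scaling. Over all alternatives, the ratio table included, 1231 of the values of these genes kept both, 615 lost the call, 10 gained one and 5 reversed. The number of changed genes stayed within 1.5 times of 5653 under each scaling, filter and probe rule, from 4458 without a filter on dim probes to 8012 with normexp, of which 3383 and 4204 were shared with the 5653. Requiring a 2-fold change left 219 genes, 181 higher and 38 lower, and 10 genes in place of 31 below background in the control group. There were 2096 genes called higher with median scaling and 2105 genes called higher with no filter, and genes called lower 3764 with median scaling and 5103 with normexp. Normexp moved the median log2 change of all genes from 0.049 to -0.062. Genes below background in the control group numbered 17 with normexp, 18 with quantile normalization, 16 with no filter and 10 without empirical Bayes moderation, which left 2 of 4 below background in the BBMP group; the filter for probes above background on all 6 arrays leaves 0 of both by construction. NRF2 targets called higher numbered 4 without moderation. Lists past the threshold numbered 3 with normexp, 2 with no filter, 0 with cyclic loess, 0 with an estimated correlation, 4 with fry and 0 with the slide row block or row 1 alone; the adjusted p of the interferon list ranged from 0.00131 to 0.864. Slide row as a block and slide row 1 alone (1 control, assumed to vary like the BBMP arrays) called 0 genes with limma, 0 higher and 0 lower, with 0 NRF2 targets and 0 genes below background in either group, and 7286 and 7176 genes at an unadjusted p under 0.05. Slide as a block was not run, since each slide holds 1 group. No label says that the replicate numbers pair the samples. Deviations of same-numbered samples from their group means correlated at -0.116, -0.082 and -0.068. With 3 arrays per group such correlations are tied together and cannot settle whether samples were paired. With the replicate block limma called 0 genes (0 higher, 0 lower, 0 NRF2 targets, 0 below background in either group), with 9949 at an unadjusted p under 0.05. Leaving out 1 array gave 3 to 4014 changed genes, 3 to 2436 higher, 0 to 1578 lower, 0 to 29 and 0 to 3 below background in the control and the BBMP group, 0 to 1 lists (0 without control replicate 1 or BBMP replicate 2) and 0 to 7 NRF2 targets, the counts of genes being lowest without BBMP replicate 2. Normexp reversed Amigo3 (-0.018), Cd5 (-0.085) and Cdc6 (-0.018), all dim. Its offset shrinks changes of dim genes by construction, which alone reverses no sign, and can also pull them toward lower in BBMP. Whether that pull gave the reversals was not tested. The mean of all probes reversed Th (-0.049) and Vegfa (0.16), whose probes differ in sign. Camera's direction turned to higher for cholesterol synthesis (adjusted p = 0.604 with normexp, 0.930 with no filter), heat shock proteins (0.779) and p53 targets (0.938) with normexp, and for G1/S transition with the slide row block (0.736) and row 1 alone (0.795). Where no construction is named, the cause was not tested. The lowest signal well above background was between -6.31 and -6.07 on BBMP and between -5.88 and -5.67 on control arrays, and a probe was tested if above background in 1 group. So the filter can favour dim probes that are higher in BBMP samples, and how much of the median change of 1.02 in the dimmest range this gives was not tested.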

Other observations

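The tests of gene families, of NRF2 targets against other named genes, of adrenal tissue and of olfactory receptor genes under other scalings were chosen after the results were seen, as were the genes named here. Kidney tubule injury markers included Havcr1, which encodes KIM-1 and was dim, at a log2 difference of 0.77 ± 0.13 (SE), Vim at 0.31 ± 0.06, Igfbp3 at 0.40 ± 0.08 and Igfbp1 at 0.34 ± 0.09, all called higher by limma, with another probe of Igfbp3 called the opposite way. Spp1 and Lcn2, of the same list, did not pass, at -0.29 ± 0.34 and 0.11 ± 0.29 (SE). Limma's fry gave the list an adjusted p of 0.0268 and camera 0.610. Among matrix, vessel and intercalated cell genes, Mmp2 rose by 0.67 ± 0.08, Cdh5 by 0.51 ± 0.07, Aqp6 by 0.76 ± 0.10 and Slc4a9 by 0.38 ± 0.06 (SE). Of the integrated stress list, Mthfd2, a mitochondrial folate enzyme, was lower, at -0.61 ± 0.07 (SE), and Psat1 at -0.39 ± 0.07 (SE), with another probe of Psat1 called the opposite way. The clock gene Npas2 was lower, at -0.88 ± 0.15 (SE).

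A hypothesis was that NRF2 targets were called higher more often than other named genes. They were in 19.4% of 36 members against 8.81% of other named genes, with an unadjusted two-sided Fisher's exact p of 0.0357. This list had been picked for its count, and the adjustment was added after that p was seen: over all 34 lists in both directions, 68 tests, the adjusted p was 0.715, so the excess did not hold. The smallest unadjusted p, 0.00544 for fatty acid and triglyceride synthesis, gave an adjusted p of 0.370.

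A further pattern is the excess of higher over lower calls among changes of at least 2-fold, 82.6% of which were higher, against 69.8% with cyclic loess and 48.1% of 27 genes with normexp. A brightness difference between the slides is a candidate explanation, and 69.8% lies between the bounds of 60% and 70% set in advance, so that test leaves it open. In counts added later, among genes well above background on all 6 arrays, 67 rose and 26 fell at least 2-fold. With cyclic loess 33 rose and 46 fell, and with quantile normalization or median scaling 42 rose and 41 fell. Among these genes the excess therefore depended on the scaling. Across 25 families named by their symbols, tested in both directions, olfactory receptor genes were called higher in 44 and lower in 6 of 255 (smallest adjusted two-sided Fisher's exact p = 0.000805); with normexp 4.71% were higher against 9.91% of other named genes (two-sided Fisher's exact p = 0.00383) and 14.5% lower against 14.7%. Within 18 ranges of brightness the excess stood at an odds ratio of 2.20 (95% interval 1.51 to 3.15; exact two-sided Cochran-Mantel-Haenszel p = 3.93e-05), and with cyclic loess 28 of 255 were higher against 7.23% of other named genes (two-sided Fisher's exact p = 0.0282). These genes are dim, with a median normalized log2 signal of -4.45, and 187 of the 255 were well above background on all 6 arrays. The filter that let in the rest can favour dim probes that are higher in BBMP samples. Matching on brightness does not remove this, and how much of the excess it gives was not tested. By construction the normexp offset shrinks changes of dim genes and can pull them toward lower in BBMP. The deficit of higher calls with normexp therefore does not decide whether the excess is real. The test within brightness ranges and the test with cyclic loess used the processed signal with its own background correction. These tests, like the Fisher's exact tests of ERCC probes and gene lists, count genes or probes of the same 6 arrays as independent. Their p-values and intervals therefore do not measure the spread between animals. Neither the test within brightness ranges nor that with cyclic loess therefore excludes brightness or background, and slide or BBMP as the source was not tested.

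The signal that Cyp11a1 gained was 0.0508 times that gained by Cyp21a1. Cyp11a1 was well above background on 4 of the 6 arrays, and the probes of Star, Cyp11b1 and Dbh on 0, with Star at a normalized log2 signal of -7.45 in control and -7.30 in BBMP samples, Cyp11b1 at -7.70 and -8.18, and Cyp11b2 at -5.53 and -5.81. Signals so near the floor decide nothing, and 6 of the 7 tested adrenal markers had a positive change, so adrenal tissue in the BBMP samples is neither shown nor excluded.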
